A study of Homo sapiens with 14 samples.

How the data were processed

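The series holds expression arrays of MCF10A cells grown as a monolayer (2D) for 2 or 5 days or in Matrigel (3D) for 8 or 16 days. The labels give 3, 3, 3 and 5 arrays for these 4 groups, and the series design states that they are biological replicates. Culture type and days in culture are not crossed. Scan dates, RNA extraction batches and the passage of the cells are not given in the sources used here. The arrays were Affymetrix HG-U133 arrays of the A type, hybridised with biotin-labelled cRNA. The deposited values are log2 expression values made with Affymetrix Expression Console by robust multi-array averaging (RMA), per the submitters' processing notes, which give no versions or settings. The values lay between 3.32 and 14.4, which fits a log2 scale, and the table held no columns of other samples. An array has no read depth. Precision therefore depends on the number of arrays, and the median standard error was 0.1 in log2 units for 3D against 2D, 0.149 for 2D day 5 against day 2 and for 3D day 8 against 2D day 5, 0.134 for 3D day 16 against day 8 and 0.2 for the difference of the later minus earlier changes.

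Of 22283 probe sets, 68 were controls, 19065 matched 1 gene in the array's annotation, 1043 matched several genes and 2107 matched none. Each of 11963 genes was given the value of the probe set that matches it alone and has the highest mean over the 14 arrays. Genes with a log2 value of 5 or more on at least 3 arrays were kept, which left 10552 genes and put 1411 under the filter. Names were compared with a table of human genes by Entrez identifier: 12 identifiers were not in it and 0 symbols were changed. No genome was used and no coordinates are given. Probe sets of close paralogs, such as the aldo-keto reductases, histones and ribosomal proteins, can measure more than 1 gene.

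One linear model with a mean for each group was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3, with moderated tests and Benjamini-Hochberg adjustment over the 10552 genes. The contrasts were the mean of the 3D groups minus the mean of the 2D groups with equal weights, 2D day 5 minus day 2, 3D day 16 minus day 8, 3D day 8 minus 2D day 5, and the later minus earlier change in 3D minus that in 2D. Genes were called at an adjusted p under 0.05, and counted again with an absolute log2 fold change of 1 or more. Before the data were examined, 32 pathway lists and 6 lists of markers of other cell types or mammary cell states were written down. The 32 pathway lists had 1083 members, of which 923 were on the array. Each list was tested with camera at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over its kind of list. Camera was also run with a correlation estimated for each list, and the rotation test fry was run. Members were counted at p-values adjusted over all genes and again adjusted over the list alone.

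Genes were named by a rule written at the same time. For 3D against 2D it took the 12 largest rises and the 12 largest falls among called genes whose arrays did not overlap between the groups, for the 3 other comparisons of groups the 10 largest of each, and for the last comparison the 5 highest and the 5 lowest called genes. For each list it took up to 4 called members with the largest absolute change, or up to 2 members given as values where none was called. Genes of interest outside it are said to have been chosen after their values were seen.

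Same-numbered arrays were checked for pairing before calls were compared. The deviations of same-numbered arrays from their group means correlated at 0.51, 0.15 and 0.17 for numbers 1, 2 and 3 between 2D day 2 and day 5, and at 0.57, 0.3 and 0.41 between 3D day 8 and day 16. For 2D day 2 they were 0.25, 0.27 and -0.02 with 3D day 8 and 0.2, 0.11 and -0.13 with 3D day 16. For 2D day 5 they were 0.17, -0.17 and -0.03 with 3D day 8 and 0.26, -0.04 and 0.04 with 3D day 16. Number 1 thus correlated across culture types as well, so pairing across them stays open. The replicate number as a block is given beside the comparisons within a culture type, where all 3 numbers correlated. With all arrays the block also joins same-numbered 2D and 3D arrays. Numbers 4 and 5 occur only in 3D day 16, so the block also takes those 2 arrays out of the estimates, and it is read beside the fit without them. The other alternatives tried were no filter, a filter at 7, the mean of all probe sets of a gene, avoiding probe sets ending in _x_at or _s_at, testing every probe set, centring each array on its median, cyclic loess, trend and robust moderation, array weights, fitting only the arrays compared, stricter thresholds and leaving out each array. Leaving out 3D day 16 replicates 4 and 5, leaving out the 3 arrays with the highest difference between 3' and 5' actin control probe sets, using that difference as a covariate, and combining the block with only the arrays compared were chosen after seeing the data.

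The model was tested on simulated values for 10552 genes of which 200 were changed. At a change of 1 log2 unit it recovered 95.5% of changed genes for 3D against 2D, 85.1% for 2D day 5 against day 2, 89.6% for 3D day 16 against day 8, 85.1% for 3D day 8 against 2D day 5 and 58.2% for the last comparison, with 11, 14, 5, 9 and 3 false calls. Camera called the 1 moved list of 32 simulated lists and none of the others. The simulated genes varied independently and without pairs, so this check cannot show how the preset correlation behaves for lists of correlated genes. Each count of calls was compared with counts from other splits of the same arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.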

Results

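Gene expression was measured in MCF10A cells, an established, non-tumorigenic human mammary epithelial cell line, grown either as a conventional monolayer (2D) or in Matrigel, a gel of basement membrane proteins in which these cells form hollow spheres (3D). RNA from 14 cultures was hybridised to 14 Affymetrix HG-U133 arrays of the A type. There were 3 arrays from 2D day 2, 3 from 2D day 5, 3 from 3D day 8 and 5 from 3D day 16, and the series design calls them biological replicates. The deposited values were log2 expression values from robust multi-array averaging (RMA), between 3.32 and 14.4, for 22283 probe sets, of which 10552 genes with 1 value each were tested. An array has no read depth, so the number of arrays limits the precision, and the median standard error of the 3D minus 2D log2 difference was 0.1. The 2D and 3D cultures were sampled on different days, so no comparison holds time constant. Culture type made up the main axis of variation: the first principal component held 55.7% of the variance and separated all 2D arrays from all 3D arrays. The second component held 12.7% and spread the 3D day 16 arrays from -22.2 to 16.7, with replicates 4 and 5 at 16.7 and 14.5 and replicates 1, 2 and 3 at -16.9, -22.2 and -16.3. Within groups, the correlation between arrays over all probe sets was lowest in 3D day 16, at 0.9674, against 0.9912 in 2D day 2, 0.9918 in 2D day 5 and 0.9843 in 3D day 8. Replicates 4 and 5 also had the highest differences between 3' and 5' control probe sets of the day 16 arrays, for actin (0.2648 and 0.1861) and for GAPDH (0.5301 and 0.4298).

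**Figure D1:**
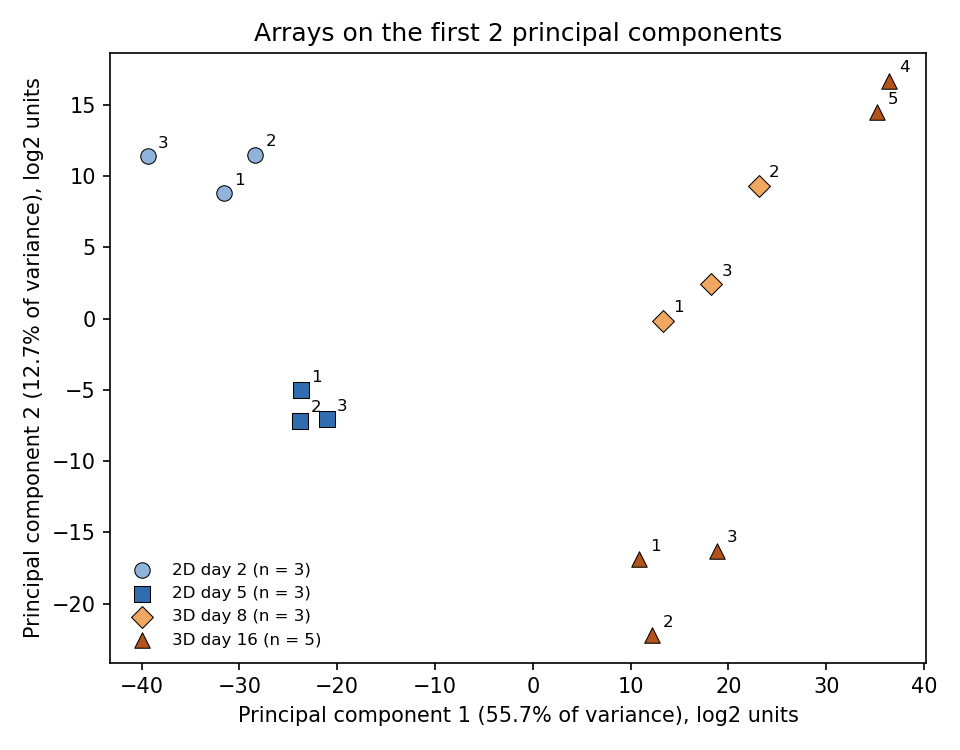
Each point is 1 array, placed by its scores on principal component 1 (x axis) and principal component 2 (y axis), both in log2 units, computed over 10552 genes, with marker and colour giving the group and the printed digit the replicate. All 2D arrays lie at -21.1 or below on component 1 and all 3D arrays at 10.9 or above, and 3D day 16 replicates 4 and 5 lie apart from replicates 1, 2 and 3 on component 2.

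The first comparison, named by the series title, asked how the 3D cultures differed from the 2D cultures. All 52 genes measured of the cell division list were lower in Matrigel, while 24 of 38 epidermal differentiation genes and 21 of 30 lysosome and autophagy genes were higher. At the nearest times, 3D day 8 against 2D day 5, the epidermal list was not called and fewer of its genes were higher than lower. No list passed with an estimated correlation between genes (adjusted p = 0.116 or more). GPNMB (Entrez gene 10457), a transmembrane glycoprotein found in melanosomes and lysosomes, rose most, 10.8-fold, from group means of 4.85 ± 0.141 (SD, n = 3) in 2D day 2 and 5.45 ± 0.374 (n = 3) in 2D day 5 to 9.32 ± 0.824 (n = 3) in 3D day 8 and 7.85 ± 0.219 (n = 5) in 3D day 16. The 2D day 2 mean of GPNMB lay under the level of 5 set for dim genes, so its fold rests in part on dim values and is less certain. ASPM (Entrez gene 259266), a spindle pole protein, fell most, 11.6-fold, with a log2 fold change of -3.53 (SE 0.324, limma adjusted p = 1.11e-06). Of the 10552 genes tested, 5548 were called at an adjusted p under 0.05, 3295 higher and 2253 lower in 3D. Of these, 133 were higher and 385 lower by at least 2-fold, so the larger changes were mostly falls. On 895 of the genes called higher and 978 of those called lower, the 8 3D arrays did not overlap the 6 2D arrays. Over all 10552 genes this held for 1878, where chance would separate 0.0666% of genes in either direction.

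Besides GPNMB, the largest rises among genes with separate arrays were those of the basal-layer keratin KRT15 (log2 fold change 2.93, SE 0.184), the protease inhibitor SERPINA3 (2.92, SE 0.199), the calcium-binding alarmin S100A9 (2.50, SE 0.257), the lipoxygenase ALOX15B (2.29, SE 0.127) and BBOX1, the last enzyme of carnitine synthesis (2.17, SE 0.216). LAPTM5, a lysosomal membrane protein (2.06), the complement protease C1R (2.05 with SE 0.221), the membrane protein PDZK1IP1 (2.00), the monoamine oxidase MAOA (1.98), the alcohol dehydrogenase ADH1B (1.81) and the complement factor CFB (1.74) followed. Limma adjusted p-values of these 12 genes lay between 2.38e-08 for ALOX15B and 0.00062 for ADH1B. The 2D means of ADH1B and the 2D day 2 mean of BBOX1 lay under 5 too, so these rises also rest in part on dim values. The falls were led by ASPM and by CEP55, which acts at the last step of cytokinesis (-3.05, SE 0.213). The mitotic kinase PBK (-2.79, SE 0.328), the centromere protein CENPF (-2.69, SE 0.184), the kinesin KIF14 (-2.65 with SE 0.149), HMMR (-2.58), GOLGA8A (-2.55), DLGAP5 (-2.54), ZWILCH (-2.40), CCNA2 (-2.40) and ECT2 (-2.36) followed. All of these except GOLGA8A, a golgin of a family of near-identical copies whose probes may be shared, act in mitosis or cytokinesis. The 12th gene was HMGCS1, the second enzyme of cholesterol synthesis (-2.42, SE 0.289). Probe sets of the same gene differed by over 1 log2 unit for CENPF (-2.69 to -0.24), GOLGA8A (-2.55 to -0.17), ADH1B (0.09 to 1.81) and CFB (0.43 to 1.74).

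**Figure D2:**
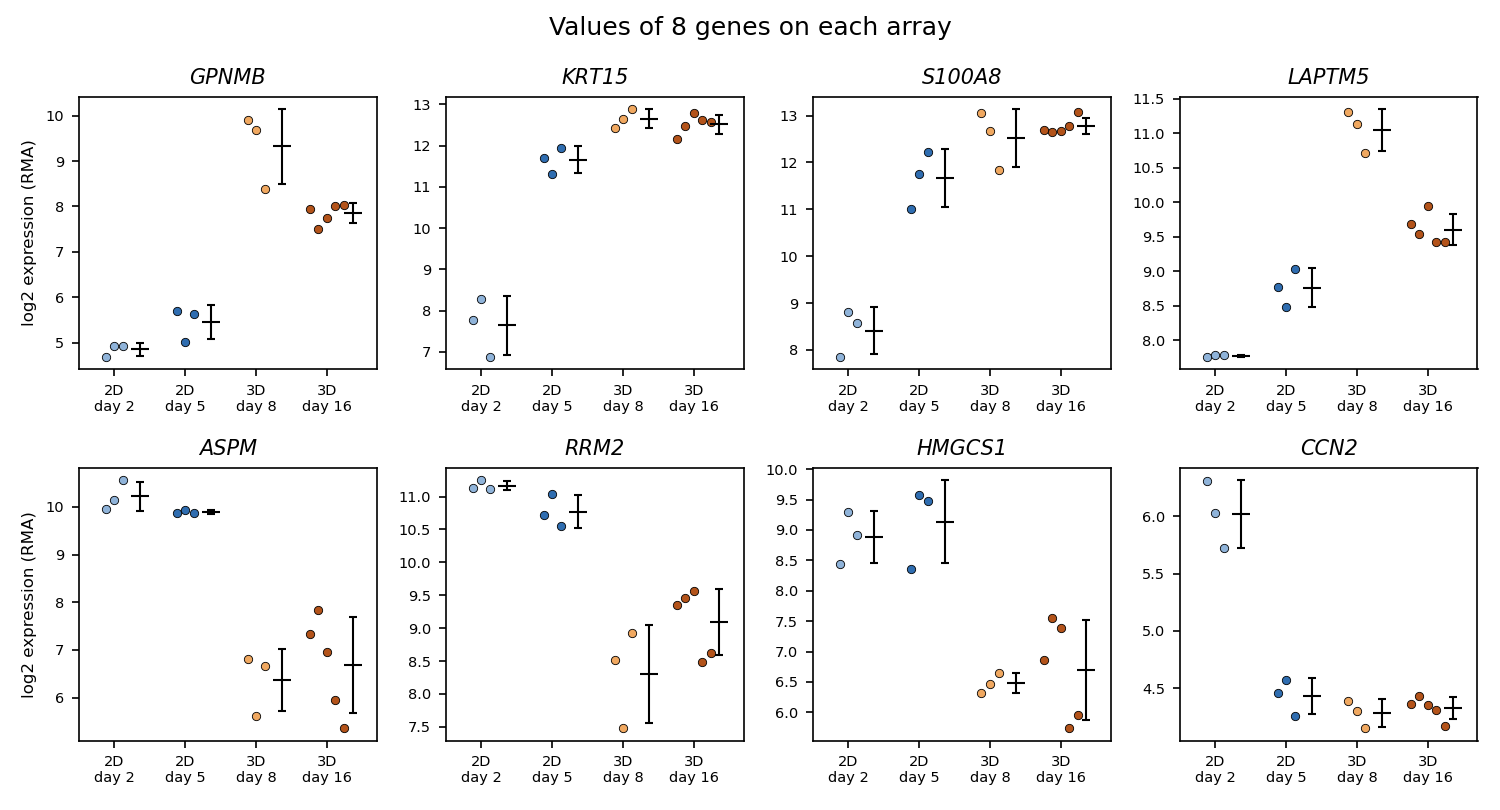
Each panel shows log2 expression (RMA, y axis) of 1 gene on every array of the 4 groups (x axis), with 1 point per array and the group mean ± SD as a black bar to the right (n = 3, 3, 3 and 5). GPNMB, KRT15, S100A8 and LAPTM5 were higher in 3D than in 2D and ASPM, RRM2, HMGCS1 and CCN2 lower, while KRT15 and S100A8 had already risen, and CCN2 had already fallen, between 2D day 2 and day 5.

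The 52 genes of the cell division list had a median log2 fold change of -1.74 in 3D against 2D, and 40 of 44 DNA replication genes were lower, among them the ribonucleotide reductase subunit RRM2 (-2.27), the origin licensing factor CDC6 (-1.92), GINS1 (-1.75) and MCM10 (-1.74). Camera, a test of a list against all other genes, gave adjusted p-values of 4.03e-35 and 3.35e-23 with a preset correlation between genes, and 0.176 and 0.116 with an estimated correlation. Of the ribosome biogenesis and MYC target list, 15 of 30 genes were lower and 2 higher (camera adjusted p = 0.000696, and 0.24 with an estimated correlation), with PUS7 at -1.20 and HSPE1 at -0.78. At the nearest times, 3D day 8 against 2D day 5, 4 were lower and 1 higher (adjusted p = 0.112). In contrast, 29 of 39 cytoplasmic ribosomal protein genes were higher and none lower (adjusted p = 3.41e-05, and 0.24 with an estimated correlation). Those rises were small, with RPL14 at 0.64 and RPS9 at 0.58 on the probe sets chosen for each gene, and the count was 18 of 39 after cyclic loess scaling. Of the quiescence and FOXO target list, 13 of 22 genes were higher and 1 lower (adjusted p = 0.0108, and 0.311 with an estimated correlation), including the antiproliferative BTG1 (1.73), YPEL5 (1.48), CITED2 (1.26) and TXNIP (1.12).

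In the cholesterol synthesis list 14 of 18 genes were lower and 1 higher (camera adjusted p = 1.02e-06, and 0.205 with an estimated correlation), with HMGCS1 followed by IDI1 (-1.64), FDPS (-1.45) and ACAT2 (-1.31). In the fatty acid synthesis list 7 of 14 were lower and 4 higher (adjusted p = 0.0289, 0.176 with an estimated correlation and 0.0952 after cyclic loess scaling), and at the nearest times 2 were lower and 1 higher (0.36). Its largest falls were those of the elongase ELOVL6 (-1.85), ACLY (-1.14), the desaturase SCD (-1.09) and FASN (-0.98), although the other probe set of FASN gave 0.28. Of the lysosome and autophagy list 21 of 30 genes were higher and 2 lower (adjusted p = 0.000823, and 0.205 with an estimated correlation), led by GRN (1.13), CTSB (1.05), LAMP2 (1.04) and GAA (0.95), and 1 of the other probe sets of LAMP2 gave -0.46.

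Of the epidermal differentiation list 24 of 38 genes were higher and 1 lower (camera adjusted p = 0.000696, and 0.262 with an estimated correlation), led by S100A8 (2.61), S100A9, the cornified envelope precursor SPRR1B (2.43) and ALOX15B, and the other probe set of S100A8 gave 1.03. At the nearest times 3 of these 38 genes were higher and 6 lower (adjusted p = 0.992). Of the NF-kB and cytokine list 17 of 29 were higher and 1 lower (adjusted p = 0.00522, and 0.205 with an estimated correlation), with CFB, the death ligand TNFSF10 (1.55), the feedback inhibitor TNFAIP3 (1.55) and C3 (1.18). Other probe sets gave 0.24 for TNFSF10 and 0.43 for CFB, and the 2D day 2 mean of TNFSF10 lay under 5. Antigen presentation genes were higher in 11 of 21 cases and lower in none (adjusted p = 0.0184, and 0.205 with an estimated correlation), including the immunoproteasome subunit PSMB9 (0.80) and the peptide transporter TAP1 (0.57). Interferon response genes were higher in 18 of 36 cases and lower in 4, with UBE2L6 at 1.37 and GBP2 at 1.24, but at the nearest times 5 were higher and 4 lower (adjusted p = 0.436). The interferon list passed at an adjusted p of 0.041, and gave 0.24 with an estimated correlation, 0.0686 after cyclic loess scaling and 0.0637 with the actin difference of each array as a covariate. Targets of the YAP and TAZ coactivators were lower in 11 of 22 cases and higher in 1 (adjusted p = 0.000316, and 0.176 with an estimated correlation), with F3 at -1.48, AMOTL2 at -0.97, CCN2 at -0.92 and CRIM1 at -0.81. The means of CCN2 lay under the level of 5 set for dim genes in all groups except 2D day 2.

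**Figure D3:**
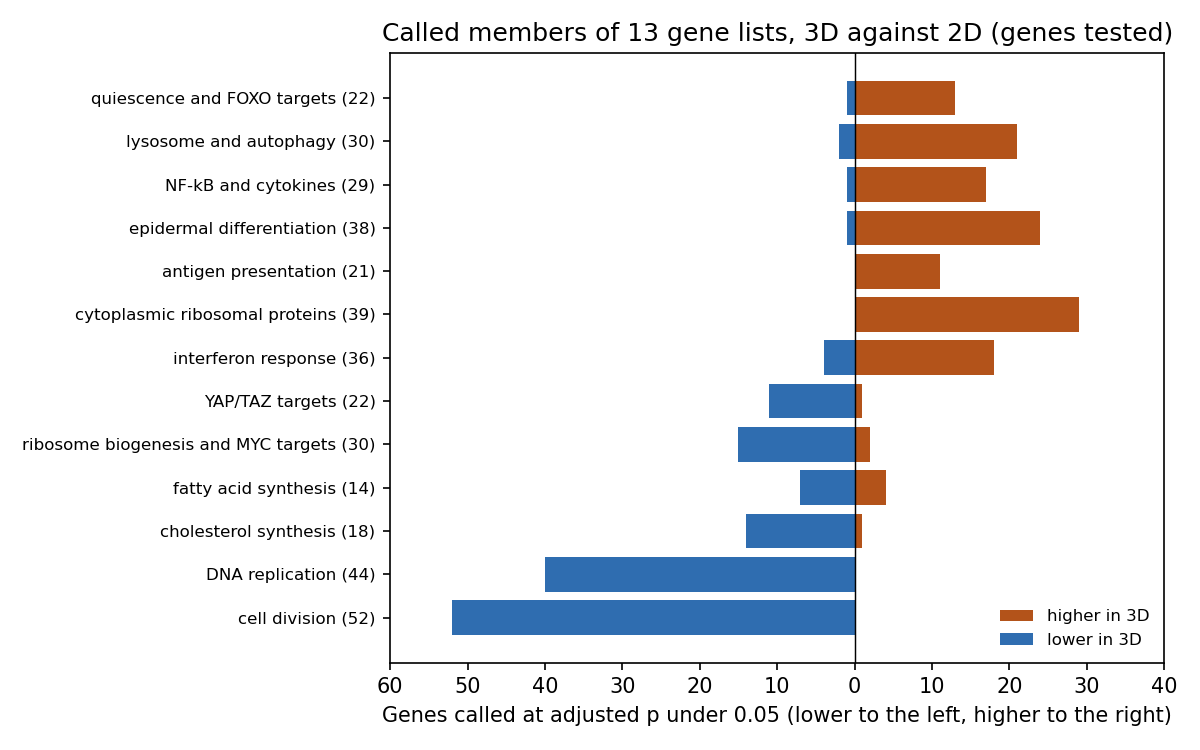
Bars count, for the 13 gene lists called by camera between 3D and 2D, the genes called lower in 3D (blue, to the left) and higher in 3D (orange, to the right) at an adjusted p under 0.05, with the number of genes tested in parentheses. The cell division list had 52 of 52 genes lower and the cytoplasmic ribosomal protein list 29 of 39 higher, but none of the 13 lists passed with an estimated correlation between genes, where adjusted p-values were 0.116 or more.

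Among mammary and structural genes the changes went both ways. Of the luminal marker list 14 of 29 genes were higher and 4 lower, but 7 and 5 after cyclic loess and 2 and 5 at the nearest times, with KRT15 up, CD24 at -2.06, KRT7 at -1.35 and EHF at -0.95, and the other probe set of KRT7 gave 0.02. The 3D means of EHF also lay under 5. Of the basal and myoepithelial list 9 of 24 were higher and 4 lower, with TAGLN at -1.71, the laminin receptor subunit ITGA6 at -1.39 and KRT16 at 1.24. KRT16 had already risen between 2D day 2 and day 5, and at the nearest times its mean was lower in 3D than in 2D. The 3D day 16 mean of TAGLN was close to its 2D day 2 mean, with 7.56, 7.75 and 7.28 on replicates 1, 2 and 3 and 4.99 and 5.19 on replicates 4 and 5. The calls of CD24 and ITGA6 were lost with the actin difference of each array as a covariate. CD24 was also uneven within 3D day 16, at 11.49, 11.44 and 10.71 on replicates 1, 2 and 3 and 7.86 and 7.76 on replicates 4 and 5. Replicates 1, 2 and 3 lay above the 2D day 2 mean of CD24, so its fall did not hold for every 3D array. Of the tight and adherens junction list 5 of 29 were higher and 9 lower, with the adhesion molecule EPCAM at -2.08 and the scaffold TJP1 at -1.05. Counts of higher and lower genes were 1 and 2 of 13 for desmosomes, 3 and 7 of 20 for hemidesmosomes and integrins, 4 and 7 of 22 for the basement membrane and 11 and 4 of 30 for proteases and inhibitors. Mesenchymal genes gave 12 and 4 of 28, with the proteoglycan DCN at 1.64 (0.50 on another probe set), and the actin cytoskeleton list 6 and 13 of 32. The metabolic and stress lists gave 8 and 7 of 34 for hypoxia and glycolysis, 13 and 3 of 37 for oxidative phosphorylation, 7 and 4 of 22 for p53 targets and 4 and 9 of 21 for the unfolded protein response. They gave 4 and 7 of 27 for the amino acid response, with the cystine transporter SLC7A11 at -2.32 (-0.50 on another probe set), and 9 and 15 of 33 for oxidant defence. Signalling lists gave 5 and 1 of 17 for the BCL2 family, 4 and 10 of 30 for EGFR ligands and ERK feedback and 10 and 3 of 23 for glucocorticoid targets. Histones gave 10 and 3 of 13, a family whose probe sets can be shared between near-identical genes. After cyclic loess the counts became 1 and 7 for the basement membrane, 3 and 1 for the BCL2 family and 2 and 11 for EGFR ligands and ERK feedback. Camera called none of these 19 lists in the fit of all arrays. The mesenchymal (0.0234), hemidesmosome (0.0197), EGFR (0.00451) and histone (0.00639) lists were called with the replicate block, which also takes 3D day 16 replicates 4 and 5 out of the estimates, and each was called without those 2 arrays, without the 3 arrays with the highest actin difference and with the actin covariate too. Histones (0.0371) were also called after cyclic loess and the actin cytoskeleton (0.0478) after centring each array. With an estimated correlation none of these calls was kept (adjusted p = 0.104 or more). Adjusted over the list alone, the counts were the same for all but 9 of the 32 lists, and among called lists they became 22 higher for lysosome and autophagy, 14 higher for quiescence and 30 higher for cytoplasmic ribosomal proteins.

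The split between higher and lower calls depended on scaling: 59.4% of called genes were higher in 3D with the deposited values and 47.1% after cyclic loess, with 2195 higher and 2462 lower. The median over all genes was 0.12 in log2 units with the deposited values and 0.04 after cyclic loess. Markers of RNA condition moved with culture type, since the difference between the 3' and 5' actin control probe sets was -0.714 ± 0.107 (SD, n = 6) in 2D and -0.164 ± 0.555 (n = 8) in 3D (2-sided exact permutation p = 0.0226, 0.0339 adjusted over 3 measures). The control probe set for Alu repeats was 13.82 ± 0.099 in 2D and 12.93 ± 0.201 in 3D. Of the lists for other cell types, fibroblast markers were higher for 4 of 8 genes and lower for 1, leukocyte markers higher for 3 of 9 and myoepithelial markers higher for 3 of 8. Endothelial markers were higher for 1 of 6, mature luminal markers higher for 2 and lower for 1 of 7, and adipocyte markers called for none of 4, where CIDEC was 0.12 and LPL 0.09 in log2 units. The 3 leukocyte genes were LAPTM5, CSF1R (0.47 with SE 0.071) and CD3D (0.40).

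The second comparison asked what changed in monolayer between day 2 and day 5. Of the epidermal differentiation list 9 of 38 genes rose. KRT15 (Entrez gene 3866) rose 16-fold, from 7.65 ± 0.713 to 11.65 ± 0.324 (SD, n = 3 each, limma adjusted p = 2.61e-06). SPRR1B rose by 3.79 log2 units (SE 0.581), the carbonic anhydrase CA2 by 3.49 (SE 0.526) and S100A8 by 3.25 (SE 0.319), although the call of S100A8 was lost when probe sets ending in _x_at or _s_at were avoided. S100P (2.50), KRT16 (2.44), S100A9 (2.26), the small heat shock protein HSPB1 (2.19), FXYD3 (1.96) and the elastase inhibitor PI3 (1.86) completed the 10 largest rises. The largest fall was that of CCN2, a matricellular YAP target, with a log2 fold change of -1.59 (SE 0.142, adjusted p = 3.36e-05), to a day 5 mean of 4.43, under the level set for dim genes. AMIGO2 (-1.33), the aldo-keto reductases AKR1C2 (-1.27) and AKR1C1 (-1.23), the EGFR ligand EREG (-1.18), ARG2 (-1.16), LRP8 (-1.10), SLC7A11 (-1.10), TAF5 (-1.09) and the mitotic transcription factor FOXM1 (-1.08) also fell. AKR1C1 and AKR1C2 are close paralogs that their probes may not tell apart, and the calls of AKR1C1 and ARG2 were also lost when those probe sets were avoided. The day 5 mean of EREG lay under 5 as well. In all, 121 genes were called, 71 higher and 50 lower, and 34 of the rises and 13 of the falls were at least 2-fold.

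By list, 9 of 38 epidermal differentiation genes rose, or 16 adjusted over the list alone, and none fell (camera adjusted p = 1.87e-15, and 0.0635 with an estimated correlation). Interferon response genes rose in 5 of 36 cases, or 12 adjusted over the list alone, including TRIM22 (1.21), IFI27 (0.78), IFITM2 (0.74) and HERC6 (0.71). The interferon list passed with the preset and with the estimated correlation (adjusted p = 2.23e-10 and 0.0145). The p53 target list did so too (0.000431 and 0.0404), although only DDB2 (0.70) and the cell cycle inhibitor CDKN1A (0.62) were called among 22 genes, or 4 adjusted over the list alone. With the replicate block, these 2 lists gave 0.0598 and 0.0926 with an estimated correlation, and without 3D day 16 replicates 4 and 5 both gave 0.0725. Luminal markers rose in 6 of 29 cases, 8 adjusted over the list alone, with MUC1 (1.51), SLPI (1.43) and KRT8 (1.15) after KRT15 (adjusted p = 5.78e-06, and 0.11 with an estimated correlation). The junction gene CLDN7 rose by 1.83. DNA replication genes fell in 4 of 44 cases, or 12 adjusted over the list alone, with CDC6 at -0.92 and MCM10 at -0.85 (adjusted p = 2.23e-10, and 0.116 with an estimated correlation). Arrays of the 2 groups did not overlap for any called gene, 71 higher and 50 lower, but called genes are picked for such a difference. Over all 10552 genes they did not overlap for 2337, where chance gives 10%. Same-numbered arrays deviated together within 2D, but the correlation was 0.51 for number 1 and only 0.15 and 0.17 for numbers 2 and 3. The own number was the best match for 2 of 3, so pairing within 2D is uncertain. With only the 6 arrays compared the count was 435 genes without and 1035 with the replicate block. With all arrays it was 414 with the block, which also takes 3D day 16 replicates 4 and 5 out, against 281 without those 2 arrays alone, and all 121 genes were among the 414 and the 1035. The count was 358 without the 3 arrays with the highest actin difference. Leaving out 2D day 2 replicate 1, 2 or 3 gave 60, 48 and 27 genes, and leaving out 2D day 5 replicate 2 or 3 gave 62 and 31.

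The third comparison asked what changed in Matrigel between day 8 and day 16. In the fit of all arrays more genes fell than rose, but without the 3 arrays with the highest actin difference 400 rose and 352 fell. TREM1 (Entrez gene 54210), an activating receptor best known from myeloid cells, rose 9.2-fold, from 7.07 ± 0.256 (SD, n = 3) to 10.27 ± 0.447 (n = 5), with a limma adjusted p of 1.31e-06. The G protein regulator RGS2 (2.17, SE 0.478), TMEM45A (1.90, SE 0.428), the alarmin S100A7 (1.45), the cornified envelope protein SPRR3 (1.36), NREP (1.32), RHOB (1.25 with SE 0.297), PTPRO (1.22), the oxygen sensor EGLN3 (1.20) and the collagen prolyl hydroxylase P4HA1 (1.18) also rose, with the day 8 mean of EGLN3 under 5. RGS2 and TMEM45A lost their calls in each fit that left out 1 day 8 array or 1 of day 16 replicates 1, 2 and 3. At day 16 RGS2 was at 11.69, 11.62 and 11.2 on replicates 1, 2 and 3 and at 9.4 and 9.3 on replicates 4 and 5. The largest falls were those of HSD17B2, which inactivates oestradiol (-2.12, SE 0.315), the arginase ARG2 (-2.02, SE 0.23) and the cyclin CCNA1 (-1.90, SE 0.182). EPCAM (-1.70), PIR (-1.57), the repressor BCL6 (-1.49), GPNMB (-1.47), LAPTM5 (-1.45), SEL1L3 (-1.43) and GCH1 (-1.42) fell too. Of 227 genes called, 53 were higher and 174 lower at day 16, and 12 and 42 of these changed at least 2-fold. Arrays did not overlap for 50 of the genes called higher and 170 of those called lower. Over all 10552 genes they did not overlap for 847, where chance separates 3.57% of genes.

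Oxidant defence genes fell in 12 of 33 cases and rose in none, or 19 and 1 adjusted over the list alone, with AKR1C2 (-1.36), AKR1C1 (-1.21), the malic enzyme ME1 (-1.05) and the glutathione synthesis enzyme GCLC (-1.03). The calls of ARG2, AKR1C1, ME1 and GCLC were lost when probe sets ending in _x_at or _s_at were avoided. Fatty acid synthesis genes fell in 5 of 14 cases, or 9 adjusted over the list alone, including ACSL1 (-1.19), ELOVL5 (-0.75) and FADS2 (-0.65). These were the 2 lists of 17 called that also passed with an estimated correlation (adjusted p = 0.00252 for each). With the replicate block and an estimated correlation they gave 0.0708 and 0.0436, against 0.0334 and 0.0174 without replicates 4 and 5 alone, and oxidant defence gave 0.068 without the 3 arrays with the highest actin difference. Hypoxia and glycolysis genes rose in 5 of 34 cases, 6 adjusted over the list alone, with NDRG1 (1.17) and PKM (0.68) besides EGLN3 and P4HA1 (adjusted p = 3.19e-05, and 0.294 with an estimated correlation). Epidermal differentiation genes rose in 4 of 38 cases and fell in 1, or 7 and 1 adjusted over the list alone, with SPRR1A at 1.66 (adjusted p = 1.42e-05, and 0.251 with an estimated correlation). Lysosome and autophagy genes fell in 4 of 30 cases, 5 adjusted over the list alone, with WIPI1 at -1.05 and SQSTM1 at -0.94 (adjusted p = 0.000673, and 0.251 with an estimated correlation). In the antigen presentation list PSMB9 (-1.39) and TAP1 (-1.27) fell, the only 2 of 21 genes called, or 3 adjusted over the list alone (adjusted p = 0.0214, and 0.251 with an estimated correlation).

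No cell division gene was called between 3D day 8 and day 16 in the fit of all arrays, where HMMR was 1.12 and TOP2A 1.06 higher in log2 units and the list median was 0.41. The list itself passed camera (adjusted p = 2.01e-10, and 0.294 with an estimated correlation). Without 3D day 16 replicates 4 and 5, 20 of 52 cell division genes were called higher (adjusted p = 0.0925 with an estimated correlation), and with the replicate block 26 of 52 were (0.15). The basal and myoepithelial list had no called gene with all arrays, with KRT16 at 1.23 and TAGLN at 1.21, but 5 of 24 genes higher without replicates 4 and 5 (adjusted p = 0.000134, and 0.0334 with an estimated correlation) and 7 with the block (5.69e-05, and 0.0708 with an estimated correlation). Histone genes went from 1 to 3 of 13 called higher without these 2 arrays (adjusted p from 0.18 to 0.000877, and 0.0334 with an estimated correlation) and also with the block (0.00166, and 0.0708 with an estimated correlation). Calls of the cholesterol, oxidative phosphorylation and unfolded protein response lists, all toward lower values at day 16, were lost without these 2 arrays (0.117, 0.0522 and 0.316) and so with the block (0.143, 0.0688 and 0.315). Calls of 2 lists, desmosomes and the actin cytoskeleton, were gained in both fits, at 0.0157 each with the block, and there gave adjusted p = 0.322 and 0.166 with an estimated correlation. Without replicates 4 and 5 the count was 788, 317 higher and 471 lower, with 219 of the 227 among them. Same-numbered arrays deviated together within 3D, and the block, which also takes these 2 arrays out, gave 1065 genes, 429 higher and 636 lower, with 223 of the 227 among them, so most of the gain did not need the pairing. The count was 752 without the 3 arrays with the highest actin difference, which are 3D day 8 replicate 1 and these same 2 arrays. In the 8 arrays compared it was 1508 with the block and 36 without it. Without 3D day 8 replicate 1 it was 67. The 227 calls rest on 1 spread per gene shared with the 2D arrays, and the 36 on the spread of the 3D arrays alone.

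The fourth comparison set the nearest times of the 2 culture types side by side, 3D day 8 against 2D day 5. It called 2024 genes, 1002 higher and 1022 lower, of which 157 and 320 changed at least 2-fold. GPNMB rose by 3.87 log2 units (SE 0.3), HSD17B2 by 3.66 (SE 0.352), SERPINA3 by 2.53, LAPTM5 by 2.29 and the histone H2AC25 by 2.04. C1R (2.01), ALOX15B (2.00), the protease inhibitor SERPINA5 (2.00), AKR1C2 (1.82) and the ribonuclease ANG (1.80 with SE 0.151) followed. CD24 (Entrez gene 100133941), a luminal surface glycoprotein, fell most, from 12.31 ± 0.305 to 7.99 ± 0.781 (SD, n = 3 each, limma adjusted p = 0.00267). ASPM (-3.53), the actin-bundling protein TAGLN (-3.41), CEP55 (-3.29), HMMR (-3.16), DLGAP5 (-2.95), CENPF (-2.87 with SE 0.274), PBK (-2.74), TOP2A (-2.67) and HMGCS1 (-2.66) also fell. Limma adjusted p-values of these 20 genes were 0.00267 or less.

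All 52 cell division genes and 38 of 44 DNA replication genes were lower at 3D day 8 than at 2D day 5 (camera adjusted p = 5.5e-46 and 1.29e-27, and 0.1 and 0.0658 with an estimated correlation). Lysosome and autophagy genes were higher in 15 of 30 cases, or 19 with 1 lower adjusted over the list alone, with LAMP2 at 1.40 and SQSTM1 at 1.12 (adjusted p = 1.49e-05, and 0.147 with an estimated correlation). Hypoxia and glycolysis genes were lower in 9 of 34 cases and higher in 2, or 11 and 3 adjusted over the list alone, with ANGPTL4 at -1.26 and P4HA1 at -1.16 (adjusted p = 0.00158, and 0.407 with an estimated correlation). Tight and adherens junction genes were lower in 8 of 29 cases and higher in 2, or 9 and 2 adjusted over the list alone, including CLDN7 (-1.46), the E-cadherin gene CDH1 (-1.27) and EPCAM (-1.24) (adjusted p = 0.0212, and 0.353 with an estimated correlation). The aldo-keto reductases AKR1C1 (1.79) and AKR1C3 (1.71) were higher and the retinaldehyde dehydrogenase ALDH1A3 (-1.79) lower, in an oxidant defence list with 7 of 33 genes higher and 3 lower that was not called. The call of AKR1C1 was again lost when probe sets ending in _x_at or _s_at were avoided. None of the 12 lists called here passed with an estimated correlation, but DNA replication passed after cyclic loess (0.0407) and after centring each array (0.0457), and lysosome and autophagy after cyclic loess (0.0281). Arrays did not overlap for 976 of the genes called higher and 1004 of those called lower. Over all 10552 genes they did not overlap for 4138, where chance separates 10% of genes. Leaving out 2D day 5 replicate 3 gave 1320 genes.

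The last comparison tested whether the later minus earlier change differed between 3D and 2D. It called 49 genes, 13 with a higher and 36 with a lower change in 3D. KRT15 had the largest difference, -4.14 in log2 units (SE 0.368, limma adjusted p = 9.94e-05), since it rose 16-fold in 2D and stood at 12.65 ± 0.235 and 12.52 ± 0.227 at the 2 times in 3D. S100A8 (-3.004), LAPTM5 (-2.44), FXYD3 (-2.35) and BBOX1 (-2.24) differed in the same direction. TREM1 (2.89), DTL, a ubiquitin ligase subunit of S phase (1.86), CCN2 (1.63), FOXM1 (1.35) and the flap endonuclease FEN1 (1.30) differed the other way. CCN2 stood at 4.28 and 4.32 in 3D, under the level of 5 set for dim genes, at both times. The calls of BBOX1 and FOXM1 were lost with no filter and with every probe set tested, and that of S100A8 when probe sets ending in _x_at or _s_at were avoided. Of the lists, 22 were called and 7 of them also passed with an estimated correlation. DNA replication went toward higher values in 3D relative to 2D, with 3 of 44 genes called, or 22 adjusted over the list alone (adjusted p = 0.0328 with an estimated correlation). Fatty acid synthesis (0.00447), interferon response (0.0107), p53 targets (0.0146), antigen presentation (0.0194), tight and adherens junctions (0.0328) and oxidant defence (0.0349) went the other way. With the replicate block, 3 of these 7 passed with an estimated correlation, fatty acid synthesis (0.0375), interferon response (0.0375) and p53 targets (0.0478), and without replicates 4 and 5 alone DNA replication (0.049) and antigen presentation (0.0355) passed too. Junctions gave 0.0685 after cyclic loess and oxidant defence 0.0511 after centring each array. The spans compared were of different length, so the test compares the sampled spans and not rates. Leaving out 3D day 16 replicates 4 and 5 raised the count to 210 genes, and the block, which also takes them out, to 310, with all 49 genes among them in both. It was 209 without the 3 arrays with the highest actin difference and 87 with the actin difference as a covariate. Leaving out 2D day 2 replicate 1, 2 or 3 gave 23, 24 and 13 genes, 2D day 5 replicate 1, 2 or 3 gave 29, 20 and 17, 3D day 8 replicate 1 gave 17, and 3D day 16 replicate 1, 2, 3 or 4 gave 23, 27, 22 and 27.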

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

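The tests of RNA quality and of position between day 8 and day 16 for the 3D day 16 arrays, of leukocytes and of other splits of the arrays were chosen only after results were seen, and so was the test of RNA quality for the dim genes. The later minus earlier change differed between 3D and 2D, by limma's test of the difference itself, for TREM1 (2.89 in log2 units), DTL (1.86), CCN2 (1.63), FOXM1 (1.35), FEN1 (1.30), KRT15 (-4.14), S100A8 (-3), LAPTM5 (-2.44), FXYD3 (-2.35) and BBOX1 (-2.24). One 3D day 16 array lay far from the other 4, by the gap to its nearest neighbour over the whole range, for 7 of 134 genes tested, where chance gives about 1 in 20, and for none of 3 array measures. The genes were AKR1C3 (ratio 0.878, replicate 4 at 10.35 against 11.09 to 11.19), ANGPTL4 (0.722, replicate 1 at 8.68 against 7.81 to 8.05), ARG2 (0.714, replicate 5 at 6.81 against 5.43 to 5.83) and CFB (0.816, replicate 4 at 7.53 against 8.17 to 8.32). The others were CTSB (0.725, replicate 1 at 11.13 against 10.51 to 10.68), FXYD3 (0.835, replicate 1 at 11.27 against 11.67 to 11.75) and S100A8 (0.714, replicate 5 at 13.07 against 12.66 to 12.78). In control probe sets outside the comparisons, the difference between 3' and 5' actin was 0.55 higher in 3D than in 2D, and the 3D minus 2D difference of the Alu control probe set was -0.886 in log2 units (exact permutation p = 0.000333, 0.000999 adjusted over 3 measures).

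Small rises of dim genes were in excess in 3D. In 5 equal bins of mean level, from dim to bright, the median 3D minus 2D difference was 0.159, 0.178, 0.113, -0.00283 and 0.00266. An intensity-dependent shift left by the normalization predicted such a shift in genes under the filter too, whose median was 0.063, and this value cannot tell that explanation from another. The 3 arrays with the highest actin difference did not account for it alone, since the median of the 2 dimmest bins was 0.153 without them and 0.168 with all arrays. The 5 3D arrays left still had a mean actin difference of -0.515, against -0.714 in 2D, so leaving out those 3 cannot exclude RNA quality. With the actin covariate, calls over all levels went from 3295 higher and 2253 lower to 2255 and 1930, and the higher share from 59.4% to 53.9%. RNA quality stays open.

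Replicates 4 and 5 of 3D day 16 stood apart from replicates 1, 2 and 3, and RNA quality stays open as an explanation: both arrays had the highest actin and GAPDH differences of day 16, while the actin slope across genes correlated at -0.245 and -0.125 with their gaps, and at -0.041 and 0.066 without 3D day 8 replicate 1, on which the slope rests. As a mislabelled time point predicted, 2 of 2 arrays lay nearer to the mean of 3D day 8 (43.4 and 35.5) than to that of the other day 16 arrays (46.3 and 42.4). On 788 genes called without them, replicates 4 and 5 lay at 0.388 and 0.27 of the way from day 8 to day 16. Each other 3D array was left out of its own fit and placed on the genes called there. Day 8 arrays lay at 0.198 to 0.281, on 752 to 782 genes, and day 16 replicates 1 to 3 at 0.822 to 1.041, on 391 to 690 genes. TREM1 was at 9.61 and 10.28 on these arrays and 7.07 ± 0.256 at day 8, and LAPTM5 at 9.42 and 9.43 against 11.06. These 2 genes were chosen after their values were seen. The rule that named them also required every day 16 array to lie on 1 side of the day 8 arrays. They therefore cannot decide against a day 8 culture. A mislabelled time point and variation between day 16 cultures, which was not tested, both stay open.

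LAPTM5, GPNMB and TREM1, which are known from macrophages and other myeloid cells, were high in 3D. As a set the 9 leukocyte markers rose less than LAPTM5, with a median 3D minus 2D difference of 0.195 against 2.06. PTPRC was at 0.17 (limma adjusted p = 0.183), with group means between 5.59 and 5.83. LAPTM5 is 1 of the 9 and was picked for its rise, so this result was nearly fixed and cannot exclude leukocytes. TREM1 and GPNMB are not on the list, so the test does not cover them. CD14 was 1.15 higher at 3D day 8 than at 2D day 5 (limma adjusted p = 0.00486). LAPTM5 was highest at 3D day 8, where FCER1G stood at -0.07 against 2D day 5 (0.73). CD14 did not follow LAPTM5 throughout. From 2D day 2 to day 5 CD14 went from 7.59 to 7.18 and LAPTM5 from 7.77 to 8.76. At 3D day 16 CD14 was at 7.2, while LAPTM5 was at 9.61.

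Other splits of the same arrays were used to ask whether grouping at random could give the counts. For 3D against 2D, 1 of 100 splits, the real one, reached 5548 genes, and the highest other gave 3444. For the difference of the later minus earlier changes, 4 of 100, the real one among them, reached 49, and the highest other gave 99. These draws did not keep same-numbered arrays in pairs, although such arrays deviated together within a culture type, so this share does not allow for pairing. For 2D day 5 against day 2 and for 3D day 8 against 2D day 5 the real split was the highest, 1 of 10 in each, with 0 genes in the highest other, which is too few splits to tell. For 3D day 16 against day 8, 3 of 56 splits reached 227, and the highest other gave 1295, so grouping at random could not be excluded for that count. Both larger splits, at 1295 and 750, set day 16 replicates 4 and 5 against replicates 1, 2 and 3, which points to that structure of the samples. Of the 8 splits that part all 3 same-numbered pairs, 2 reached 227, the real one and the one at 750. The replicate block, which also takes replicates 4 and 5 out of the estimates, gave 1065, against 788 without those 2 arrays alone.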

How the results depend on the processing

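No named gene with a call reversed under any setting, and at 2-fold more genes were lower than higher in 3D than in 2D under every setting. Of all genes called between 3D and 2D 59.4% were higher with the deposited values and 47.1% after cyclic loess, and between 3D day 16 and day 8 23.3% were higher with all arrays and 53.2% without the 3 arrays with the highest actin difference. The 74 genes named between 3D and 2D include CIDEC and LPL, given without a call. The called ones kept their calls wherever they were tested, except CD24 and ITGA6 with the actin covariate. The 38 named between 3D day 16 and day 8 include HMMR, TOP2A, KRT16 and TAGLN without a call. Of the 38, 16 lost their calls with only the arrays compared, and 14 did without 3D day 8 replicate 1, as many as without replicate 2. Of the 33 named between 2D day 5 and day 2, 19 lost theirs without 2D day 2 replicate 3 and 18 without 2D day 5 replicate 3, among them S100P, KRT16, PI3, CDKN1A and FOXM1. Without 2D day 2 replicate 1 or 2, 12 and 15 lost theirs, and without 2D day 5 replicate 1 or 2, 12 and 11 did. ARG2, IFI27, DDB2, CDKN1A, MUC1 and KRT8 lost theirs in each fit that left out 1 2D array. Of the 10 named for the difference of the changes, BBOX1, FOXM1 and FEN1 lost their calls in 12, 10 and 9 of the 14 fits that leave out 1 array. The fit of all arrays uses 1 spread per gene for all groups, whose lowest correlations within a group were 0.9912 and 0.9918 in 2D and 0.9843 and 0.9674 in 3D. The 227 calls of 3D over time thus rest in part on the spread of the 2D arrays. The 121 calls of 2D over time likewise rest in part on the spread of the 3D arrays. Counts that moved by over 1.5 times follow, and where no cause is named the cause was not tested. For 3D against 2D the count was 3438 at an adjusted p under 0.01, 518 at 2-fold, 3527 with a filter at 7, which tests fewer genes, and 9082 with every probe set, which tests more. For 2D day 5 against day 2 it was 26 at 0.01, 47 at 2-fold, 451 with array weights, 435 with only the arrays compared, 414 with the replicate block, which also takes 3D day 16 replicates 4 and 5 out, and 1035 with both. For 3D day 16 against day 8 these were 43, 54, 376, 36, 1065 and 1508. For 3D day 8 against 2D day 5 it was 1026 at 0.01, 477 at 2-fold, 3054 with every probe set and 3280 with the block. For the difference of the changes it was 12 at 0.01, 30 with no filter, 132 with array weights and 310 with the block. Chosen after seeing the data, leaving out 3D day 16 replicates 4 and 5 gave 281 for 2D over time, 788 for 3D over time and 210 for the difference of the changes, leaving out the 3 arrays with the highest actin difference, which include those 2, gave 358, 752 and 209, and the actin covariate gave 87 for the last. Leaving out 1 array at a time gave 4468 to 5834, 27 to 146, 67 to 337, 1320 to 2266 and 13 to 68 genes for the 5 comparisons in this order, and 12 to 17 lists. Of the 13 lists called between 3D and 2D, 0 passed with an estimated correlation, and fry called 27 lists. Fry asks whether the members of a list change at all, not whether they change more than other genes. With 5548 of 10552 genes called, its 27 lists cannot be set against the 13 of camera. Fitting only the arrays compared was not run where all 4 groups are used, nor were the thresholds for genes and the test of every probe set for the lists. Dim genes are limited by signal over background, and the filter left out 1411 genes.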

Other observations

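The test of whether the 2D change recurs in 3D was planned before its result was seen, but its condition on splits that part the pairs was added after, and without it the hypothesis fitted. Values of 3D day 16 replicates 1 to 5 follow for 6 genes chosen after they were seen, with no test of a gene group. KRT14, a basal keratin, was at 12.37, 12.45, 12.66, 9.74 and 8.96. LOX, a collagen cross-linking enzyme, was at 9.39, 10.24, 9.66, 5.82 and 5.81, and DCN at 10.57, 10.91, 10.59, 8.55 and 8.68. CD24 was at 11.49, 11.44, 10.71, 7.86 and 7.76, and TAGLN at 7.56, 7.75, 7.28, 4.99 and 5.19. KRT15 was at 12.16, 12.47, 12.78, 12.61 and 12.57.

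One hypothesis was that the later change in 2D recurs between day 8 and day 16 in 3D. Of the 121 genes called between 2D day 5 and day 2, 69.4% had the same sign in 3D, and 2 of 56 splits of the 3D arrays reached that share, with 71.1% in the highest other. Same-numbered 3D arrays deviated together, and only 8 splits part all 3 pairs, of which the real one was the highest (65.3% in the next), too few to tell, so the hypothesis stays open. Of 15 genes called in both, ETHE1, NDRG1 and TXNIP were higher in both, where 0.36 genes were expected by chance, and AKR1C1, AKR1C2, ARG2, C2CD2, DAPK1, KCNS3 and SLC6A15 were lower in both, where 0.82 were expected. CBR3, CLU, CXCL1, DTL and LAPTM5 went opposite ways, where 1.42 were expected. The expected counts take calls in the 2 comparisons as independent, but both use 1 spread per gene from 1 fit, so they may be too low. Genes with opposite changes exceeded their expected count too, and probes may not tell AKR1C1 and AKR1C2 apart.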
